A study of Anopheles gambiae with 6 samples.

How the data were processed

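RNA from 3 preparations of dissected embryos and 3 of serosa was compared, all 10.5 h old and fixed in formaldehyde. Per the labels' protocols and the series' design text, RNA was extracted with a kit for fixed tissue, amplified and labelled with biotin by an Affymetrix kit, and hybridized to Affymetrix Plasmodium-Anopheles arrays, 1 per preparation. Per the labels, the 3 arrays of a group are biological replicates. The labels describe the embryos as dissected. One sentence of the design text names them whole embryos, and the labels were followed.

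The values analysed are log2 expression values that the authors computed with RMAExpress, per the series' design text. This method corrects the background, normalizes the arrays to 1 distribution of values and summarises the probes of each probe set. The program's version and its probe set definitions are not given in the sources used here. The probe values of each array are forced to 1 distribution before they are summarised into probe sets. A change in the total RNA per preparation therefore cannot be read from these values, and large rises in some probe sets lower the others. The arrays give no read depth, and their number limits the precision. Columns of values not used numbered 0. No 2 arrays of a group shared more than a fraction of 0.000474 of their Anopheles values exactly, so no array was treated as a duplicate.

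Probe sets were sorted by their IDs into 16884 of Anopheles, 4502 and 4 with the prefixes Pf and Pfa of Plasmodium, 290 with IDs of human arrays, 144 controls and 937 named by sequence accessions. Arm and class (coding sequence, UTR or neither) were read from the Anopheles IDs, and no coordinates were used. A table of 15165 genes of the RefSeq assembly idAnoGambNW_F1_1 was compared with the IDs, and 0 of them matched. Gene names, counts of genes and the gene lists fixed before the data were examined were therefore not used here. Single probe sets were named by the fixed rule: past the threshold, with no overlap between groups, and the largest log2 difference in each direction. Because the files do not pair IDs with genes, only the first 2 in each direction are printed, and the parts of the rule that need gene names were not applied.

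Differences were fitted to the Anopheles probe sets with lmFit and eBayes of limma 3.58.1 in R 4.3.3, with group as the only term, and called at a Benjamini-Hochberg adjusted p under 0.05. The fold threshold was 2. The p-values measure the spread between the 3 replicates of each group. Control and accession-named probe sets were tested in a fit to all probe sets of the array. Single values per array were compared by two-sided exact permutation tests, whose smallest p for 3 against 3 is 0.1. Shares of calls were compared by Fisher's exact test over probe sets, which are not independent replicates, and sets by limma's camera with a preset correlation of 0.01 and with an estimated one. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

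The unspecific level, the 95th percentile of the Plasmodium probe sets, was fixed before the data were examined. Plasmodium sequence is rich in A and T, and the Plasmodium probe sets were dimmer than those of the human arrays. The human-probe level was therefore added after the data were seen. It would hold true signal if the preparations carried human RNA, which was not excluded, and the bright set and the bounds on folds would change with it. A control for the human Alu repeat measured 5.67 to 11.8 over the 6 arrays. The control for the 3' end of human beta-actin measured 3.72 ± 0.10 in embryo and 3.90 ± 0.03 in serosa (SD, n = 3 each), under the unspecific level of each array. Other human controls were brighter. The 5' and middle beta-actin controls lay over the unspecific level on all 6 arrays. The 3' GAPDH control measured 6.95 ± 0.17 in embryo and 6.95 ± 0.25 in serosa, over the human-probe level of each array. Bright probe sets are those whose mean over all 6 arrays exceeds the mean human-probe level, 3876 or 23.0% of those tested.

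The replicate numbers were checked for pairing across the groups. Deviations from the group means correlated between embryo and serosa arrays of the same number with r of 0.324, 0.328 and 0.222 across probe sets, and between -0.281 and -0.071 for other pairs. The deviations sum to zero within each group, so positive r for the same numbers force negative ones among the other pairs. The other pairs are therefore not separate evidence. So few arrays can be matched across the groups in only a few ways, and probe sets are not independent replicates. This check therefore cannot decide whether the numbers pair the samples. The labels do not say what same-numbered samples share.

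The fit was tested on simulated data made from the means and spreads of the 16884 probe sets, with 200 of them changed. It called 67.0% of the 103 probe sets with a simulated log2 difference of 1 and 96.9% of the 97 with a difference of 2. Of its 167 calls, 4 were false. Camera, run on simulated values of the 3876 bright probe sets with an X-linked shift of 0.3, gave the X an adjusted p of 8.83e-22 and called 0 other sets higher. The simulated values were drawn independently for each probe set and array. They hold no correlation between probe sets and no deviations shared by arrays. The simulations therefore show that a known shift is recovered, and not the rate of false calls in correlated data.

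Alternatives fixed before the data were examined were a filter at the unspecific level, equal Plasmodium medians, quantile normalization of the Anopheles probe sets alone, equal medians above the unspecific level, an eBayes trend with robust settings, array weights, the replicate number as a block, and leaving out each array in turn. Added after the data were seen were a filter at the human-probe level, equal medians of the bright probe sets, equal hybridization controls, a fit to all probe sets of the array, 1 probe set per arm and number for the comparisons of arms and classes, all Anopheles probe sets in place of the bright ones for the same comparisons, and the block for the control probe sets and for camera. For the named probe sets, a fold is given as at least that against the dimmer group with each value under the human-probe level of its array raised to it. The settings fixed for counts of genes and for gene lists were not run, since no ID matched the gene table.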

Results

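Expression was measured in the serosa and in the embryo of the malaria mosquito Anopheles gambiae (Kisumu strain) 10.5 h into development. The serosa is the epithelium outside the embryo proper that encloses it beneath the eggshell and, in mosquitoes, secretes a chitin-containing cuticle. Embryos were dissected by hand from formaldehyde-fixed eggs, and the eggshells left behind, which carried the serosa, gave the serosal RNA. The data comprised 6 Affymetrix Plasmodium-Anopheles arrays, 3 of dissected embryos and 3 of serosa. Each array held 22761 probe sets, of which 16884 belonged to Anopheles and 4502 to Plasmodium, a parasite that the labels do not list in these samples. All values are on the log2 scale of the robust multi-array average (RMA). Array maxima lay between 14.3 and 15.2. The files do not pair probe set IDs with gene names, so most results are given for probe sets and for the groups that their IDs name.

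A pair of reference levels marked unspecific signal on each array. The 95th percentile of the Plasmodium probe sets, called the unspecific level, lay between 3.87 and 4.02. The 95th percentile of the 290 probe sets that carry IDs of human arrays, called the human-probe level, was higher, between 6.10 and 6.47. The number of Anopheles probe sets above the unspecific level was 14779 ± 395 (SD, n = 3) on the embryo arrays and 14721 ± 323 (n = 3) on the serosa arrays, a difference smaller than the spread between replicates (two-sided exact permutation test, p = 0.9). Above the human-probe level there were 4145 ± 321 probe sets in embryo and 3531 ± 113 in serosa (n = 3 each). Every serosa array had fewer than every embryo array, and the two-sided exact permutation p of 0.1 was the smallest that 3 arrays against 3 allow. The level itself was higher on every serosa array (6.32 to 6.47) than on every embryo array (6.10 to 6.29). These counts therefore do not separate fewer expressed transcripts from a higher cutoff.

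The arrays grouped by tissue. Across Anopheles probe sets, which are not independent replicates, Pearson's r lay between 0.984 and 0.986 among embryo arrays, between 0.968 and 0.984 among serosa arrays, and between 0.897 and 0.954 across the groups. The first principal component held 72.4% of the variance and separated the embryo arrays (-35.3, -39.3 and -45.6) from the serosa arrays (38.5, 58.5 and 23.2). The serosa arrays were therefore more widely spaced. Among the 3876 probe sets whose mean over all 6 arrays exceeded the mean human-probe level, called bright below, the median SD between replicates was 0.31 in serosa and 0.23 in embryo.

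The comparison of serosa with embryo addressed which transcripts distinguish the extraembryonic epithelium from the embryo it encloses. The serosa held a set of transcripts at far higher levels than the embryo. In the values as deposited, decreases were more numerous and smaller, but which direction was more numerous depended on the scaling of the arrays. Of the 16884 Anopheles probe sets, 2093 (12.4%) differed at an adjusted p under 0.05 in limma, 609 higher in serosa and 1484 lower. Differences of at least 8-fold were found in 128 probe sets, all higher in serosa. The median log2 difference was 1.67 among the probe sets that were higher and -1.02 among those that were lower, and the extremes were 5.78 and -2.46. At least 2-fold differences were found in 1186 probe sets, 424 higher and 762 lower. All 2093 showed no overlap between the replicates of the groups, as did 5115 (30.3%) of all Anopheles probe sets, where chance gives 10%. In a separate limma fit to the Plasmodium probe sets, 0 of 4502 passed and 218 had an unadjusted p under 0.05. In a limma fit to all probe sets of the array, 3 Plasmodium probe sets passed (2 higher, 1 lower) and 1 of the 290 human-array probe sets.

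The counts depended on single arrays. Without embryo replicate 2, 990 probe sets passed (312 higher, 678 lower), 732 of them by at least 2-fold (288 higher, 444 lower). Without embryo replicate 3, 972 passed (325 higher, 647 lower), 674 of them by at least 2-fold (292 higher, 382 lower). Without serosa replicate 1, 1254 passed, 402 higher and 852 lower. The share of higher calls among the 2093 was 29.1%, and it followed the scaling of the arrays. It was 38.6% after quantile normalization of the Anopheles probe sets alone, 69.8% with the median of the bright probe sets equalised, and 12.2% with the hybridization controls equalised. For differences of at least 2-fold the share was 35.8%, and under these scalings 51.2%, 68.4% and 12.2%. The share of 12.2% stayed the same because every call under that scaling differed at least 2-fold, so its p-values acted much like a fold limit. The median log2 difference of all Anopheles probe sets, 0.01 as deposited, became 0.33 with bright medians equalised and -0.59 with hybridization controls equalised. The excess of rises among differences of at least 8-fold did not depend on the scaling, unlike that at 4-fold. Over these and the other settings tried, left-out arrays included, 83 to 169 probe sets were at least 8-fold higher and 0 at least 8-fold lower, with 1 lower when hybridization controls were equalised. At least 4-fold differences numbered 257 higher and 7 lower as deposited, and 180 higher and 255 lower with hybridization controls equalised. Leaving out 1 array gave 3 to 45 lower, the most without serosa replicate 3. With values of the dimmer group under the human-probe level raised to it, 98 of the called probe sets were at least 8-fold higher and 0 at least 8-fold lower. The bound can only shrink a fall, and 0 falls reached 8-fold as deposited. It therefore tests the rises alone.

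**Figure D1:**
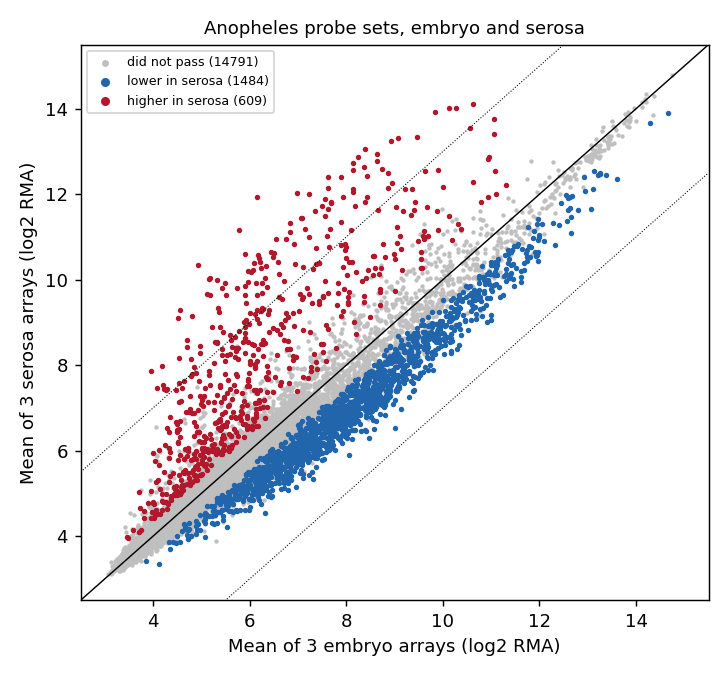
Mean of the 3 serosa arrays against the mean of the 3 embryo arrays for each of the 16884 Anopheles probe sets, in log2 RMA units, with the 609 probe sets higher and the 1484 lower in serosa in colour; the solid line marks equal levels and the dotted lines 8-fold differences. The probe sets beyond the upper dotted line have no counterpart beyond the lower one.

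The strongest rises named here started near or under the human-probe level in embryo. The largest was that of Ag.3L.920.0_CDS_s_at, which measured 6.16 ± 0.24 in embryo and 11.9 ± 1.08 in serosa (SD, n = 3 each), a log2 difference of 5.78 (SE 0.49, limma adjusted p = 0.00146). It was over the human-probe level on 2 of the 3 embryo arrays. With values under that level raised to it the rise was at least 51.1-fold (40.5-fold without serosa replicate 1 and 78.6-fold without serosa replicate 3). Next was Ag.2R.1851.0_CDS_at, which measured 4.94 ± 0.82 in embryo, under the human-probe level on all 3 arrays, and 10.3 ± 1.68 in serosa, a log2 difference of 5.41 (SE 0.82, limma adjusted p = 0.00846). Against the human-probe level in place of its embryo values, it was at least 17.8-fold higher (11.8-fold without serosa replicate 1 and 34.6-fold without serosa replicate 3). Among all rises, 114 probe sets were under the human-probe level on every embryo array and over it on every serosa array. A further 199 were over that level on all 6 arrays. Under the lower, unspecific level, 8 of the 609 lay at or below it on all embryo arrays.

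The strongest decreases ended near the human-probe level in serosa, and both named here were over it on 2 of the 3 serosa arrays. Ag.2L.2624.0_CDS_at went from 9.0 ± 0.49 in embryo to 6.54 ± 1.04 in serosa (SD, n = 3 each), a log2 difference of -2.46 (SE 0.51, limma adjusted p = 0.0243), and at least 4.30-fold lower with serosa values under the human-probe level raised to it. This call was lost without embryo replicate 2 (-2.35, limma adjusted p = 0.0881) and without embryo replicate 3 (-2.29, adjusted p = 0.0982). Ag.3L.510.0_CDS_at went from 8.47 ± 0.24 to 6.30 ± 0.65, a log2 difference of -2.17 (SE 0.32, limma adjusted p = 0.00752), and at least 3.77-fold lower with the same bound. Of the 1484 decreases, 828 were over the human-probe level on all 6 arrays and 215 were over it on every embryo array and under it on every serosa array. Among bright probe sets, 1138 (29.4%) were lower in serosa and 369 (9.52%) higher.

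Actin and Gapdh, a cytoskeletal protein and a glycolytic enzyme, were the Anopheles genes that the control probe sets name, and none of their probe sets passed the threshold. The actin probe set at the 3' end measured 13.5 ± 0.05 in embryo and 13.7 ± 0.34 in serosa (SD, n = 3 each), a log2 difference of 0.27 (limma adjusted p = 0.467). The middle actin probe set measured 11.3 ± 0.03 and 11.04 ± 0.24, a log2 difference of -0.31 (limma adjusted p = 0.255). The Gapdh probe set at the 3' end measured 8.95 ± 0.15 and 8.56 ± 0.26, a log2 difference of -0.38 (limma adjusted p = 0.218). The 5' probe sets of both genes lay under the human-probe level on all 6 arrays.

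Probe sets whose IDs name the X chromosome fell less often in serosa than those of the autosomal arms 2L, 2R, 3L and 3R. The comparisons of arms and of probe set classes were chosen after the data were seen. Of 308 bright X-linked probe sets, 51 (16.6%) were lower in serosa, against 30.5% of the 3568 other bright probe sets (odds ratio 0.453, Fisher's exact test, p = 1.02e-07, adjusted over 12 tests 1.11e-06). As a set, the X-linked probe sets stood above the rest in limma's camera test of 9 sets with the preset correlation of 0.01 (adjusted p = 0.00215) and not with an estimated correlation (adjusted p = 0.40). The 242 bright probe sets labelled UNKN in place of an arm also fell less often, with 37 (15.3%) lower (odds ratio 0.415, Fisher's exact test, adjusted p = 1.11e-06), while 6.61% were higher (odds ratio 0.658, adjusted p = 0.280). Over all UNKN probe sets rises were less frequent than elsewhere, 1.75% against 3.85% (odds ratio 0.446, Fisher's exact test, adjusted p = 1.58e-06), and the bright UNKN set did not pass in camera (adjusted p = 0.118 with the preset correlation and 0.40 with an estimated correlation). Of the 1938 UNKN probe sets 242 were bright, and decreases among the 1938 were also less frequent (2.63% against 9.59%). This comparison was not matched by level. Arm 2R had decreases in 382 of 1154 or 33.1% (odds ratio 1.29, Fisher's exact test, adjusted p = 0.00415), but did not pass in limma's camera test (adjusted p = 0.408 with the preset correlation and 0.95 with an estimated correlation). Rises were more frequent on the X, at 45 of 308 or 14.6% against 9.08% (odds ratio 1.71, adjusted p = 0.00938), but not with 1 probe set per arm and number (odds ratio 1.53, adjusted p = 0.0781), with the hybridization controls equalised (odds ratio 1.5, adjusted p = 0.188) or over all Anopheles probe sets (4.35% against 3.54%, odds ratio 1.24, adjusted p = 0.268). The odds ratio of a decrease on the X stayed under 1 and past the threshold in all settings and with each array left out. The shares of decreases were lower without embryo replicate 2 (7.79% of X-linked and 15.7% of autosomal probe sets), without embryo replicate 3 (7.47% and 14.97%) and without serosa replicate 1 (8.44% and 20.3%).

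The array values gave the same order. The median deviation of the bright X-linked probe sets from their means over all 6 arrays, minus that of the autosomal ones, was -0.20 ± 0.09 in embryo and 0.18 ± 0.01 in serosa (SD, n = 3 each). The difference of 0.39 on the log2 scale had a two-sided exact permutation p of 0.1, the smallest possible here. The same test gave the same p for UNKN (0.28), 2R (-0.04) and 3R (0.04), so the p does not single out the X. The median of X-linked minus autosomal differences was 0.01 at mean levels from 4 to 5, 0.51 from 7 to 8, 0.53 from 8 to 9 and 0.20 above 10.

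**Figure D2:**
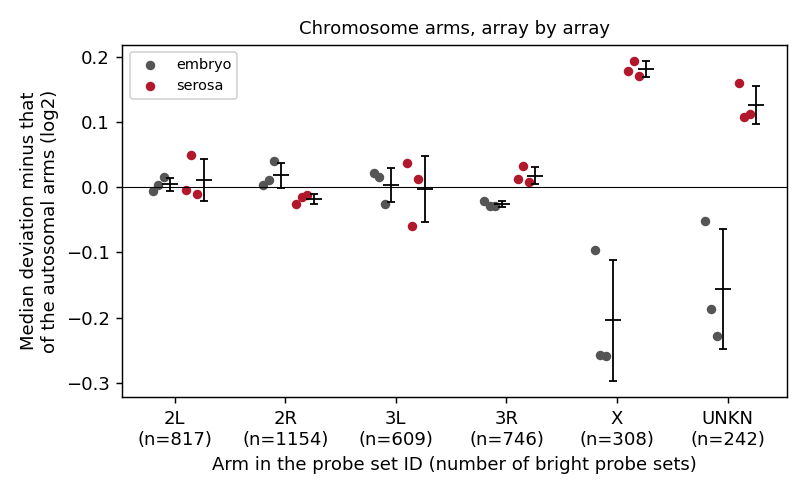
Median deviation of the bright probe sets of each arm on each array, minus that of the autosomal arms (for an autosomal arm, the other autosomal arms), in log2 units; points are arrays and bars the mean ± SD of 3 arrays. X-linked probe sets lie at -0.20 ± 0.09 in embryo and 0.18 ± 0.01 in serosa, and the UNKN probe sets at -0.16 ± 0.09 and 0.13 ± 0.03.

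**Figure D3:**
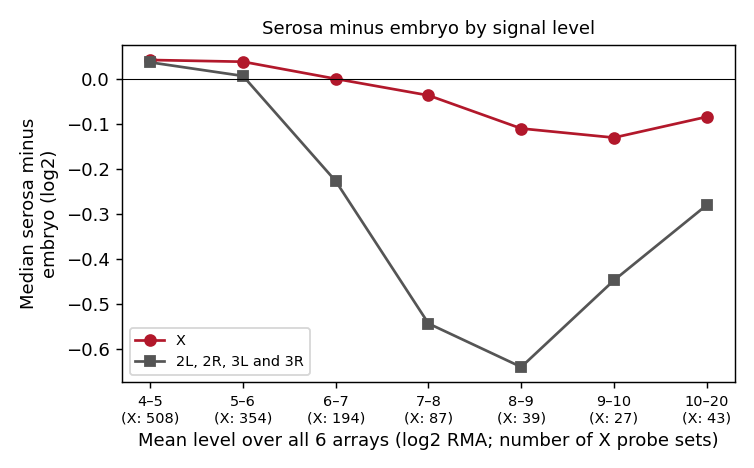
Median log2 difference, serosa minus embryo, of X-linked and autosomal probe sets in bins of the mean level over all 6 arrays. The X-linked medians stay between -0.13 and 0.04, while the autosomal ones reach -0.64 in the bin from 8 to 9.

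Among bright probe sets, those of coding sequence fell more often than those of untranslated regions (UTRs), by the class in their IDs, and over all Anopheles probe sets the direction was the opposite. Of 2515 bright coding probe sets, 32.9% were lower in serosa and 8.63% higher, whereas of 493 bright UTR probe sets 18.3% were lower and 15.01% higher. The odds ratio of a decrease, coding over UTR, was 2.20 (95% interval 1.72 to 2.84, Fisher's exact test, p = 2.47e-11), and that of a rise was 0.535 (0.400 to 0.721, p = 3.87e-05). Over all probe sets 7.99% of 14060 coding and 13.0% of 790 UTR probe sets were lower (odds ratio 0.580, Fisher's exact test, p = 2.86e-06). The UTR probe sets were also brighter, with a median level of 8.95 against 7.35 among the bright ones and 7.51 against 4.81 among all. The odds ratio of a rise was no longer past the threshold without embryo replicate 2 (0.744, Fisher's exact p = 0.110), embryo replicate 3 (0.705, p = 0.0584) or serosa replicate 1 (0.813, p = 0.255). In camera the UTR set stood above the rest with the preset correlation (adjusted p = 0.0283) and not with an estimated one (adjusted p = 0.95).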

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

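These values come from probe sets outside the comparison of Anopheles transcripts, and their tests were chosen after the data were seen.

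A control probe set for the human Alu repeat gave signal on all arrays, 9.72, 6.26 and 5.67 in embryo and 11.8, 8.63 and 10.6 in serosa. The log2 difference was 3.14 (SE 1.22, limma adjusted p = 0.211). In the limma fit with the replicate number as a block it passed (SE 0.58, adjusted p = 0.0321), with differences of 2.08, 2.37 and 4.97 within the 3 same-numbered pairs. The 18 hybridization control probe sets, whose targets are added to the sample before hybridization, averaged 9.54 ± 0.12 in embryo and 10.1 ± 0.64 in serosa (SD, n = 3 each), a log2 difference of 0.60 (exact permutation test, p = 0.3), with differences of 0.38, 1.25 and 0.16 within the 3 pairs (exact sign permutation test, p = 0.25, the smallest that 3 pairs allow). Of the 937 probe sets named by sequence accessions, 7 passed the threshold, 5 higher in serosa by 0.34 to 3.38 and 2 lower with log2 differences of -0.39 and -1.47, and 9 passed with the block.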

How the results depend on the processing

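Over the alternatives that keep all arrays, the total count of changed probe sets was 1794 to 2725 except with equal medians of the bright probe sets, where it was 3283 (2290 higher, 741 of them at least 2-fold, and 342 at least 2-fold lower). With hybridization controls equalised 312 were higher and 2241 lower, and all 2553 differed at least 2-fold. That scaling adds the same shift to all probe sets of an array. The controls had an SD of 0.64 between serosa arrays, against a median SD of 0.31 for bright probe sets. The calls then act much like a fold limit, and these counts are not tests comparable with the other settings. Quantile normalization of the Anopheles probe sets alone gave 474 at least 2-fold lower. Bright probe sets had a median log2 difference of -0.37 as deposited, -0.20 after that normalization, -0.05 with their medians equalised and -0.97 with the controls equalised. The cause was not tested beyond the shift that each scaling applies. These scalings of the bright medians and the controls, and all settings for arms and classes, were chosen after the data were seen.

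Leaving out 1 array gave 972 to 1977 changed probe sets, 312 to 682 higher and 647 to 1477 lower. At least 2-fold counts were 674 to 1376, with 288 to 538 higher and 382 to 883 lower. Fewer arrays leave fewer degrees of freedom, but the loss was uneven, with 990 without embryo replicate 2, 972 without embryo replicate 3 and 1254 without serosa replicate 1. All 4 named probe sets kept their calls under the 11 alternatives with all arrays. One call, of Ag.2L.2624.0_CDS_at, was lost without embryo replicate 2 (adjusted p = 0.0881) or embryo replicate 3 (0.0982), where its adjusted p ranged from 0.0213 to 0.0982 over the left-out arrays.

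With the replicate number as a block, 2725 probe sets changed, 749 higher and 1976 lower, 1365 of them at least 2-fold (483 higher, 882 lower). The block changed no call of the named probe sets, of the X-linked and class odds ratios or of the sets tested with camera (adjusted p = 0.0032 for the X with the preset correlation and 0.96 with an estimated one). It did bring the Alu control past the threshold (adjusted p = 0.0321).

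The X-linked minus autosomal median difference, 0.36, was 0.34 to 0.46 with an array left out and highest without embryo replicate 1. The odds ratio of a decrease on the X was 0.382 to 0.497 with an array left out. The odds ratio of a rise on the X, 1.71, was 1.80 to 2.09 with an array left out. It missed the threshold with 1 probe set per arm and number (1.53, adjusted p = 0.0781) and with hybridization controls equalised (1.5, adjusted p = 0.188). Over all Anopheles probe sets in place of the bright ones it also missed it (1.24, adjusted p = 0.268), and the odds ratio of a decrease, coding over UTR, reversed from 2.20 to 0.580. Coding over UTR among bright probe sets, the odds ratio of a decrease was 1.59 to 3.08 and that of a rise 0.392 to 0.813 with an array left out. Background limits the size of many changes: 114 rises started under the human-probe level on all embryo arrays and crossed it on all serosa arrays, and 215 decreases crossed it the other way. At the lower, unspecific level 8 rises and 4 decreases were so bounded. The settings fixed for genes and gene lists were not run.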

Other observations

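The splits of the arrays, the tests on the X-linked probe sets and the matching of bright UTR probe sets by level were fixed before their results were seen, and the other tests here were chosen after.

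Probe sets that share an arm and a number moved together. Across 1405 such numbers with 2 probe sets, the log2 differences correlated with r = 0.48, and in the 56 where both passed the threshold, all 56 pairs had the same direction. Neighbouring numbers on an arm showed little relation, with r between -0.01 and 0.07 across the 6 groups of IDs. These r are across probe sets, which are not independent replicates.

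The real grouping of the 6 arrays gave 2093 changed probe sets in limma. Of the 10 ways to split the arrays into 3 and 3, 1 gave as many, the real one. The highest of the others was 0, with up to 960 at an unadjusted p under 0.05. The 3 others that part every numbered pair, as the real one does, also gave 0, with up to 313 unadjusted. With 10 splits no share under 0.05 can be reached. Every other split mixes the tissues within its groups. This widens the spread that limma divides by, so the 0 calls of those splits say little about chance.

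As deposited, falls in serosa stayed smaller than rises (7 fell and 257 rose at least 4-fold, but 255 and 180 with hybridization controls equalised), and serosa replicates differed in the size of both. A floor of unspecific signal is argued against as the whole cause, since of 726 decreased probe sets with an embryo mean over 8, 2 (0.275%) had a serosa mean at or under the mean human-probe level of all arrays, and of 312 bright enough to fall 8-fold above the serosa level, 0 did (largest fall -1.98). Differing amounts of embryonic tissue in the serosa preparations cannot be told apart from a difference between the arrays as the source of the second difference. For probe sets chosen on serosa replicate 1 alone, the rises on replicate 3 minus those on replicate 2 had a median of -1.16 (95% bootstrap interval -1.25 to -1.05), where the falls imply at most -0.34 if signal is proportional to RNA, but 0.09 (0.01 to 0.20, falls implying at most -0.69) once the hybridization controls, which are not tissue RNA and averaged 9.56 on replicate 3 and 10.8 on replicate 2, were equalised. Both of these medians compare 1 array with 1 other, so their intervals hold the spread between probe sets, which are not independent, and none between arrays. A constant share of embryonic RNA in every serosa preparation was not settled. A share of 18.2% would set the largest mean fall. The largest falls on serosa replicates 1, 2 and 3 would imply 7.90%, 12.3% and 25.2%. If signal is proportional to RNA, replicate 1 allows a constant share of at most 7.90%, too small to set the largest mean fall. These shares rest on single extreme values, and no independent measure of the share was analysed here, so this explanation stays open. The untested difference between the tissues also stays open.

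Bright X-linked probe sets fell less in serosa than autosomal ones. A random draw of probe sets of this level is argued against, since 0 of 10000 level-matched autosomal sets reached the X-linked median of -0.06 (the highest was -0.19), but such draws leave out correlation between genes, and chance in a correlated set stays open (camera adjusted p = 0.40 with an estimated correlation). A different mix of probe classes or shared probes is argued against as the whole cause, since among plain coding probe sets the X-linked minus autosomal difference was 0.59 (95% bootstrap interval 0.44 to 0.72). Unspecific signal on X-linked probe sets cannot be told apart from this, because among the 70 with a mean over 9 the difference was 0.21 with an interval from -0.01 to 0.65. A candidate explanation that stays untested is a tissue difference, such as fewer embryo-biased genes on the X, and the UNKN probe sets showed a shift of 0.28 in the same direction.

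Among bright probe sets, coding ones fell more often than UTR ones, and over all Anopheles probe sets less often (odds ratio 0.580). For the bright ones, the higher level of UTR probe sets is argued against, since 0 of 10000 coding sets of the same levels had as low a share of falls as the bright UTR probe sets (18.3%, against 27.8% to 40.6%), but chance in a correlated set stays open (camera adjusted p = 0.95 with an estimated correlation). Over all probe sets, the opposite direction is in line with level, since 10000 of 10000 coding sets of the same levels fell more often (18.6% to 27.3%) than the UTR probe sets (13.0%). Shorter RNA in the serosa preparations, which should raise UTR signal over coding signal, is argued against as a shift common to them. For 132 pairs of one ID the UTR minus coding signal was 1.69 ± 0.04 in embryo and 1.69 ± 0.12 in serosa (SD, n = 3 each), a difference of -0.0023. Serosa replicates 1, 2 and 3 measured 1.69, 1.81 and 1.56, so this mean does not exclude shorter RNA in a single preparation. The 3' minus middle signal of actin was higher on every serosa array than on every embryo array (2.13 ± 0.04 in embryo, 2.71 ± 0.48 in serosa, exact permutation test, p = 0.1, the smallest possible). That of Gapdh did not differ beyond its spread (1.76 ± 0.28 and 1.59 ± 0.27, exact permutation p = 0.6). Actin thus went the way that shorter RNA would give. The kinds of genes with UTR probe sets, a tissue difference, were not tested here.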
